A study of Pinus canariensis with 18 samples.

How the data were processed

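Total RNA from cambium and differentiating xylem of Pinus canariensis was labelled with 1 dye and hybridised to a custom Agilent array with 180032 spots, 18 arrays in all, 3 for each of 6 dates. Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.7.3.1 and protocol GE1_107_Sep09. They hold each spot's intensity, and the processed intensity was background-subtracted and detrended by that software, with low values replaced by a surrogate, per the file headers, and was not normalized between arrays. The authors also deposited a value table on the log2 scale, and the submitters' processing notes name limma, with no version and no role. Tested on the values, every column of that table had a median of 11.25 and the table lay closest to background-corrected signals (normexp, offset 50) with quantile normalization, with a median absolute difference of 0.0253, so it was used only as an alternative.

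The main values were log2 of the processed signal minus the 75th percentile of each array's log2 signals. Of the spots, 175092 were not controls, and they held 44698 probes for 22236 gene names. Spots flagged as outliers were left out (1.45% to 3.04% per array) and the remaining spots of a probe were averaged. A probe counted as well above background on an array where more than 0.5 of its spots did, and it was kept if it did so on all 3 arrays of at least 1 date, which left 37667 probes. For each gene the kept probe with the highest mean over the 18 arrays stood for it, giving 19369 genes, of which 18267 had at least 1 further kept probe, and 5 probes with no unflagged spot on some array were left out. Where no probe of a gene was well above background on an array, a bound on the fold was computed by raising its value there, where lower, to the lowest value of any probe well above background on that array. A fold given as at least some value is this bound on the main values. It leaves out the sampling error and is no strict lower limit. With normexp and quantile normalization, every named contig with such a bound changed by less than its bound.

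Differences between dates were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 18 arrays with the date as the sole term, so that the dates shared 1 estimate of the spread with 12 residual degrees of freedom and a prior worth 2.05. A moderated F test compared the 6 dates, and 6 contrasts compared successive dates and September with March. A Benjamini-Hochberg adjusted p under 0.05 made a call, and limma's p-values were two-sided. The files were read with the R package data.table, version 1.17.8, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. On simulated data for April minus March, 200 genes among 19369 were changed. This fit recovered 20% of the genes changed by 1 on the log2 scale and 62% of those changed by 2. It recovered 78% of those changed by 3 and 92% of those changed by 4, with 7 false calls among 133. The real contrast called 3603 genes, which loosens the cut on the unadjusted p, so its recovery may differ from these shares.

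Before the data were examined, 28 lists of genes (wood formation, cell division, hormones, stress and others) were fixed as patterns to be matched to gene descriptions. As the description of every probe was Unknown, the 28 lists matched 0 genes and none could be tested. In their place, 8 groups were formed from readable names, after the names were seen and before any value was compared between dates, together with classes given by the first letters of contig names. Groups with at least 3 members and the classes were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation, with adjustment over 84 tests. The rule for naming genes was, for probes without description, at most 2 names that rose and 2 that fell per contrast, those with the largest fitted change among called genes whose 3 arrays of one date all lay beyond the 3 of the other, or the 3 smallest p-values where no gene passed. Readable transcripts were named with their group.

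The arrays lay on 5 slides, and on each slide the earlier dates held the lower positions. Comparisons within a slide therefore cannot fully tell date from position. March and April shared 2 slides that held no other date, and May, June, July and September shared the other 3, so slide was tried as a random block (correlation -0.083) and, where the layout allowed it, as a fixed block. Alternatives were the background correction and normalization, the filter on dim probes, the rule for several probes, the deposited value table, the variance model, slide and replicate blocks, only the arrays of the dates compared, and each array left out in turn. For the genes shared by April minus March and September minus March, the March arrays were also divided between the contrasts, and 1 fit exchanged the labels of June replicate 3 and July replicate 3. The replicate numbers were not treated as pairs. No sample was left out of the main fit, and gene functions beyond the readable names were not used here.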

Results

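Gene expression was measured in the vascular cambium and the xylem cells forming from it in young Canary Island pines (Pinus canariensis) grown in containers. The cambium is the thin layer of dividing cells that makes wood, and xylogenesis is the process by which its daughter cells become xylem. Samples were taken at 6 dates of a growing season, March, April, May, June, July and September, when the trees were 36, 37, 38, 39, 40 and 42 months old. Each date had 3 biological replicates by the series' design text, and each sample was hybridised to 1 array, giving 18 one-colour arrays. The labels do not say whether the replicates were separate trees, so the p-values measure the spread between these samples, which may include technical spread. The median processed signal of the arrays ranged from 2144 to 3624, the share of spots well above background from 80.8% to 86.3%, and no spot was saturated.

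The array held 44698 probes for 22236 gene names, of which 19369 genes were tested. All 44698 probes carried the same empty description, so most genes are known here only by the name of a contig and are given by that name. A small set of 47 transcripts had readable names, and 44 of them were measured: 10 phytochromes, 6 cryptochromes, 5 actins, 6 named for GA3PDH or GapC, 7 named for translation, 6 drought-named transcripts, 2 named Gs1, and 1 each for alpha-tubulin and ubiquitin. The labels do not say whether numbered names, such as PpterPhyP1 to PpterPhyP4, are separate genes or parts of 1 transcript. Among phytochrome and cryptochrome names differing only in the number, the March mean rose with it, from -6.88 for PpterPhyP1 to 0.71 for PpterPhyP4. Counts of group members are therefore counts of names, which may not be separate genes. Levels are log2 signals minus the 75th percentile of the array, so 0 is the level of a gene at that percentile.

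The arrays of March, and most of April and May, resembled the other arrays of their date, and later dates were less distinct. April replicate 2 and July replicate 2 correlated at 0.950 with each other across genes and at no more than 0.787 with any other array. June replicates 1 and 2 correlated at 0.991, above the other pairs of replicates, and were kept as 2 samples because the labels give them so. Their squared difference was 1.98 times that from the spread between spots, against 3.95 or more in the other pairs, which does not tell 1 RNA from 2. June replicate 3 correlated at 0.918 with July replicate 1 and at 0.897 on average with the other June arrays. July replicate 3 correlated at 0.903 on average with June replicates 1 and 2 and at 0.847 with July replicate 1. Besides these, 3 arrays correlated more on average with another date than with their own: July replicate 1 with April (0.926 against 0.847), September replicate 3 with May (0.928 against 0.904) and September replicate 2 with June (0.917 against 0.915). Counts of genes are therefore also given without April replicate 2 and July replicate 2, and without these and replicate 3 of June and July. The latter fit leaves July with replicate 1 only, and June with replicates 1 and 2.

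**Figure D1:**
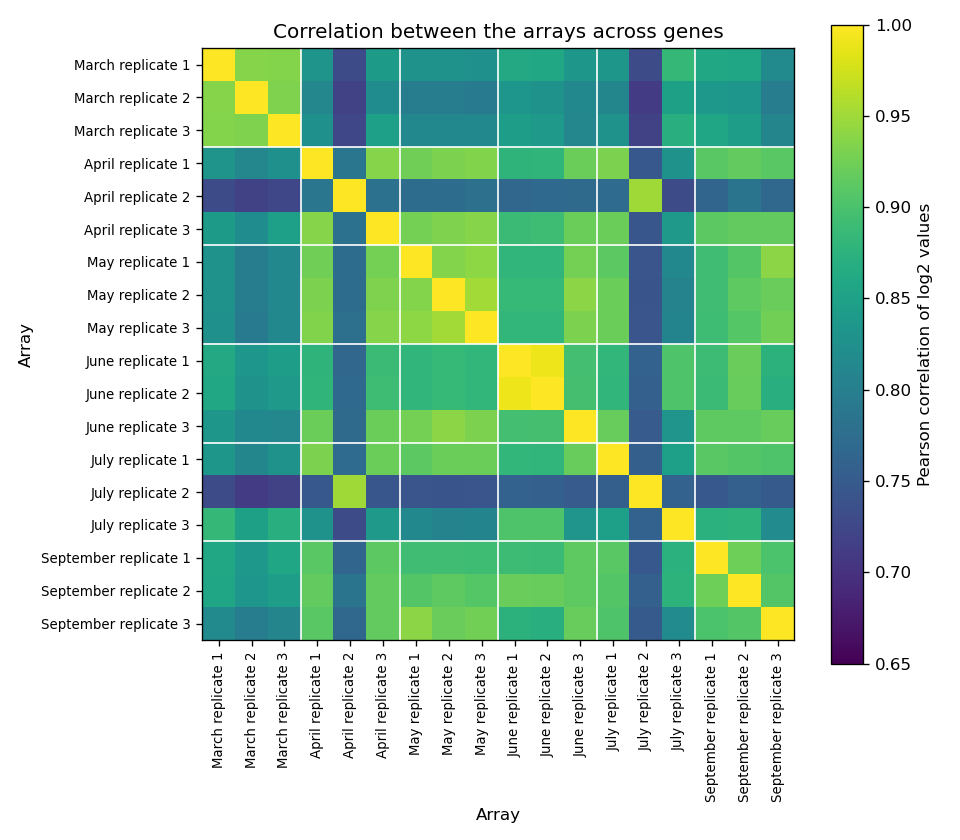
Pearson correlation across the 19369 genes between each pair of the 18 arrays, with arrays in date order on both axes and white lines between dates. April replicate 2 and July replicate 2 form dark bands and match only each other (0.950), and June replicates 1 and 2 form the brightest pair (0.991).

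The first question was which genes differed between any of the dates. March was the date that differed most in pattern from the rest: of the 3826 genes that passed limma's moderated F test, 1386 (36.2%) had their highest date mean in March and 1723 (45%) their lowest. The number highest in March was 857, 617 and 820 without March replicates 1, 2 and 3, and 2154 without the 4 arrays that stood apart. May came next, with the highest mean of 937 genes and the lowest of 685. Among the readable names, Ppterpp2c, named for a protein phosphatase 2C, fell from -0.69 ± 0.75 in March to -2.84 ± 0.13 in May (SD, n = 3 each), with an F test adjusted p of 0.00242. The phytochromes, which are receptors for red and far-red light, had 4 of 10 measured members passing, the same number as when adjusted over the list alone. Each of these, PpterPhyO2, PpterPhyP1, PpterPhyP2 and PpterPhyP3, had a lower mean in April, May and June than in March, and PpterPhyP1 was well above background on no May or June array. PpterPhyP2 went from -3.15 ± 0.07 in March to -4.32 ± 0.46 in June and -2.94 ± 0.35 in July (SD, n = 3 each; adjusted p = 0.0138).

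The remaining readable groups had fewer members passing the F test. Of the cryptochromes, which are receptors for blue light, PpterCryA1 alone passed, with its lowest mean in May (-4.34 ± 0.21) and its highest in September (-2.78 ± 0.32), and no member passed when adjusted over the list alone. Ppterrd21 joined Ppterpp2c among the 6 drought-named transcripts, and 1 of 7 translation names (PsitcheIF4B1), 1 of 6 GA3PDH and GapC names (PtGA3PDH) and the alpha-tubulin transcript also passed. Neither the 5 actins nor the Gs1 pair had a member passing over all genes tested, and adjusted over the list alone 1 Gs1 transcript did. A total of 7144 genes had an unadjusted p below 0.05. The 3826 genes at an adjusted p below 0.05 became 2119 without March replicate 2, 2432 without March replicate 3 and 6184 without the 4 arrays that stood apart.

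The comparison of April with March asked how expression changed as the season opened. Of the readable transcripts, alpha-tubulin, a building block of microtubules, rose by 1.20 ± 0.34 on the log2 scale (SE, 3 arrays per date; limma adjusted p = 0.0245). A total of 7 others fell: Ppterpp2c by 1.51, PsitcheIF4B1 by 1.27, Ppterrd21 by 0.94, PpterPhyO2 by 0.85, Ppterlp33 by 0.79, Ppteractinpicea2 by 0.71 and PptereIF4 by 0.59, with adjusted p between 0.00291 and 0.0437. Across 22 alternatives PpterPhyO2 lost its call in 17, Ppterlp33 in 12, Ppteractinpicea2 and PptereIF4 in 9 each, PsitcheIF4B1 in 7, alpha-tubulin in 4, Ppterrd21 in 3 and Ppterpp2c in 1. Over these the change ranged from -0.99 to -0.61 for PpterPhyO2, from -0.93 to -0.52 for Ppterlp33 and from -0.89 to -0.59 for Ppteractinpicea2. The range was -0.71 to -0.45 for PptereIF4 and -1.57 to -0.98 for PsitcheIF4B1, while PsitcheIF4B2 differed by -0.26 in the main fit. Among contigs without a readable name, C-isotig06399_B9R8V6 and T-isotig14821_CBI40790 were well above background on no March array and on all 3 April arrays, and rose at least 508-fold and at least 509-fold. Their date means were the same to the digits given (-9.35 in March and 1.09 in April for both). The labels do not say whether they are separate transcripts, so counts of genes may hold repeats. In the other direction, T-isotig15634_XP_462594 fell at least 3742-fold and C-isotig13130_B8LL11 at least 653-fold, each being well above background on 3 March arrays and 1 April array. The folds leave out the sampling error, which on the log2 scale was 2.3 for each rise and 2.92 and 2.01 for the falls (SE). With normexp and quantile normalization the rises were 7.47 and 7.45 and the falls -10.45 and -7.83. None of these 4 calls was lost in any of 21 alternatives.

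This was the largest change between successive dates, with 3603 genes called, of which 1835 rose and 1768 fell. At least a doubling was seen in 1582 of the risen genes and at least a halving in 1079 of the fallen ones. The 3 March values did not overlap the 3 April values in 98.4% of the called genes and in 36.9% of all genes tested, where chance alone gives 10%. A further probe of the gene was available for 3452 of the called genes, and its change had the same sign in 3375 of them (97.8%). All 10 phytochromes had a lower April mean, with a median difference of -0.58, and 5 were called lower when adjusted over the list alone, but the group's camera test did not pass (adjusted p = 0.22, and 0.912 with an estimated correlation). Among names differing only in the number, the difference shrank as the number rose. It went from -1.21 for PpterPhyP1 to -0.13 for PpterPhyP4 and from -0.85 for PpterPhyO2 to -0.25 for PpterPhyO4. For PpterPhyN2 and PpterPhyN4 it was -0.58 and -0.04, and the cause of this pattern was not tested. Of the drought-named transcripts, 3 of 6 fell (Ppterpp2c, Ppterrd21 and Ppterlp33), and the other 3 had higher April means without passing.

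March and April arrays shared 2 slides. The called genes were chosen on these same arrays, so their signs within a slide are no separate test: 3603 of 3603 had the sign of the pooled change on the slide holding 2 arrays of each date, and 3600 on the other. Across all genes, which are not independent replicates, the changes on the slides correlated at 0.597 (Spearman 0.564). The median SD between the spots of a probe was 0.177 to 0.33 on the March arrays and 0.063 to 0.102 on the April arrays. April arrays also held later positions than March arrays on each slide, so date and position are not fully told apart. With slide as a fixed block, which keeps this limit, 3217 genes were called. The count was 3701 without April replicate 2 and July replicate 2, although PpterPhyO2, Ppteractinpicea2 and the 2 translation names that fell were then no longer called (adjusted p = 0.0515, 0.0526, 0.0632 for PsitcheIF4B1 and 0.0531 for PptereIF4), while 1 cryptochrome was called lower and 1 translation name higher. It was 1820 when only the 6 arrays of these dates entered the fit and 2304 without March replicate 2.

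**Figure D2:**
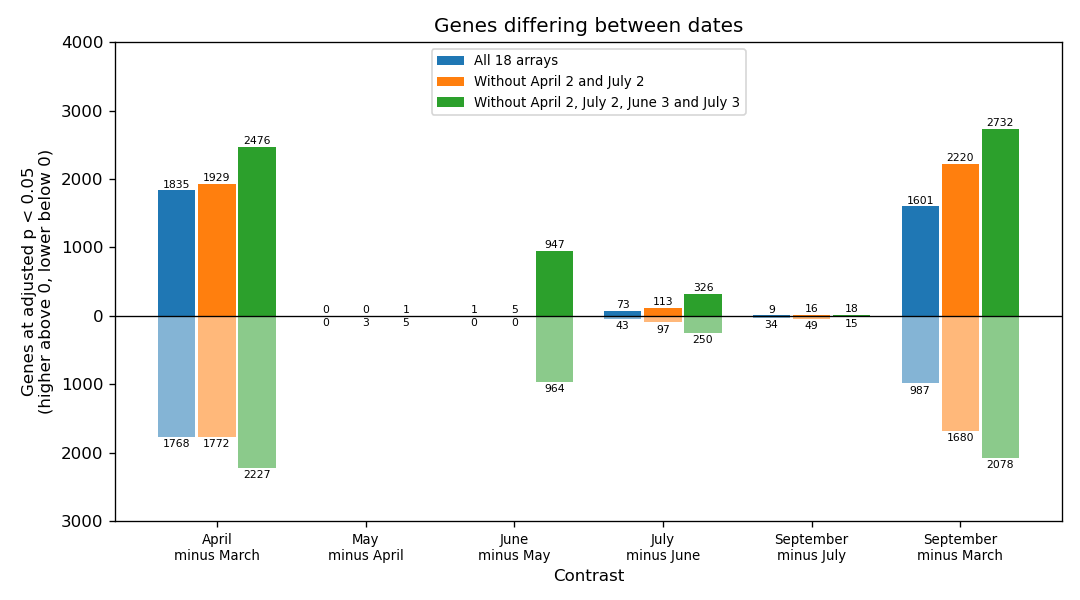
Number of genes at adjusted p below 0.05 in each contrast, with genes higher at the later date above 0 and genes lower below 0, for all 18 arrays and for the fits without the arrays that stood apart. Without the 4 arrays July is 1 array, assumed to vary like the rest. The April minus March and September minus March contrasts carried most calls, 3603 and 2588 with all arrays, and June minus May went from 1 to 1911 without 4 arrays, where June is only the nearly identical replicates 1 and 2.

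No gene was called between April and May. The smallest p belonged to T-isotig03656_ACU18601, which was 4.07 ± 0.60 lower in May on the log2 scale as fitted (SE; adjusted p = 0.158). It was well above background on 1 May array, which gave a bound of 12.4-fold, and with normexp and quantile normalization its difference was -2.35. T-isotig16462_ABK26630 was above background on no May array and at least 75.9-fold lower (adjusted p = 0.252), and gained a call in 4 of 20 alternatives, among them the fit of these dates alone (adjusted p = 0.037) and the fits without the 2 and the 4 arrays that stood apart. T-isotig04085_XP_001695795 differed by -1.98 ± 0.35 (SE; adjusted p = 0.252), and its other probe by -0.37, with a call gained in 1 of 21. All 7 translation names had a higher mean in May, with a median difference of 0.23, and 5 of the 6 cryptochromes a lower one, with a median of -0.58, and neither group's camera test passed (adjusted p = 0.32 and 0.117).

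The 50 transcripts whose names begin with SPI, a prefix that the files do not explain, had a median difference of -0.46 and passed camera's test with its preset correlation (adjusted p = 0.00344) but not with an estimated correlation (adjusted p = 0.912). Without April replicate 2 and July replicate 2 the SPI median was -0.29 and the group no longer passed (adjusted p = 0.349), nor did it pass without April replicate 3 or May replicate 2. The count of 0 came from limma, with 1739 genes at an unadjusted p below 0.05. It was 7 when the fit held only the arrays of these dates, 1 without April replicate 1, without April replicate 2 or without May replicate 2, and 3 and 6 without the 2 and the 4 arrays that stood apart. April and May arrays shared no slide, so slide and date cannot be told apart here.

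Between May and June the transcript T-isotig03656_ACU18601 rose from -7.75 ± 0.67 to -2.72 ± 0.45 (SD, n = 3 each), at least 24-fold given that it was above background on 1 May array (adjusted p = 0.0143). With normexp and quantile normalization it rose by 3.14 on the log2 scale, against 5.02 in the main fit. It was the same transcript that had the smallest p between April and May, and the only gene called, with the call lost in 9 of 21 alternatives. No readable transcript passed. The GA3PDH and GapC names had a median difference of 1.06 with 3 of 6 members higher, and adjusted over the list alone 1 was called higher; among the actins 1 of 5 was called lower on that basis. Ptactin1 differed by -0.67 (adjusted p = 0.304 over all genes).

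A total of 2287 genes had an unadjusted p below 0.05 in this contrast. The number of called genes depended on June replicate 3: without it 124 genes were called, and without any of the 4 arrays that stood apart 1911 (947 higher and 964 lower in June), among them 3 of 10 phytochromes that were higher and 1 of 5 actins that was lower. In that fit 1 of the tubulin and ubiquitin pair was also lower, and 1 of 6 GA3PDH and GapC names and 1 of the Gs1 pair were higher. With only the arrays of these dates, June replicate 3 included, 47 genes were called (33 higher and 14 lower). The 124 genes called without June replicate 3 leaned the other way, with 35 higher and 89 lower. With the labels of June replicate 3 and July replicate 3 exchanged 1540 genes were called. In the fits without June replicate 3 June consisted only of the nearly identical replicates 1 and 2, so its spread may be understated, and with these averaged as 1 sample among otherwise all arrays the count was 0. It was also 0 without May replicate 1, June replicate 1 or June replicate 2. May and June shared 2 slides, on which the changes across all genes correlated at 0.179 (Spearman 0.226), and the called transcript rose on both.

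From June to July, PpterPhyP2 rose by 1.38 ± 0.28 on the log2 scale (SE; adjusted p = 0.0453), while the difference was 0.15 (adjusted p = 0.902) with the labels of June replicate 3 and July replicate 3 exchanged. PpterPhyP2 was the only readable transcript to pass over all genes tested. The differences of PpterPhyP1, PpterPhyP3 and PpterPhyP4 were 1.81, 0.93 and 0.24. Of the phytochromes, 8 of 10 had a higher July mean, with a median difference of 0.32, and 3 were called higher when adjusted over the list alone. All 6 cryptochromes had a higher July mean, with a median of 0.65, and none passed. Both groups passed camera's test with its preset correlation (adjusted p = 0.0439 and 0.0451) and neither did with an estimated correlation (adjusted p = 0.912 for each). Without April replicate 2 and July replicate 2 the medians were 0.09 and 0.40 and neither group passed (adjusted p = 0.397 and 0.349). PpterPhyP2 was then at an adjusted p of 0.0711 and lost its call in 15 of 22 alternatives. With the 4 arrays left out July was 1 array, and the phytochrome and cryptochrome medians were 0.12 and -0.16. The group calls were also lost without June replicate 3, July replicate 2 or July replicate 3 alone. With the labels exchanged the medians were 0.00 and -0.06.

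Among the contigs, C-isotig04549_B9RQT7 rose by 4.49 ± 0.59 (adjusted p = 0.00469) and C-isotig11407_P12810 by 4.41 ± 0.91 (adjusted p = 0.048), both well above background on all 6 arrays. T-isotig03498_ABK20952 fell at least 12.8-fold (adjusted p = 0.0453) and Ppisotig01084_B9RWL3 at least 12.3-fold (adjusted p = 0.0237), each being above background on 1 July array. Their log2 changes were -4.73 and -3.96 in the main fit and -2.71 and -2.34 with normexp and quantile normalization. The call was lost in 3 of 22 alternatives for C-isotig04549_B9RQT7 and 12 of 22 for C-isotig11407_P12810, and in 11 of 21 for T-isotig03498_ABK20952 and 9 of 21 for Ppisotig01084_B9RWL3. All 4 calls were lost with the labels of June replicate 3 and July replicate 3 exchanged (adjusted p = 0.259, 0.536, 0.46 and 0.881). The log2 changes were then 2.66, 1.89, -2.32 and -0.48, in the same order. In all, 116 genes were called, 73 higher and 43 lower in July, and a further probe had the same sign in 112 of the 113 genes that had one. A total of 3161 genes had an unadjusted p below 0.05. The count was 9 without June replicate 1, 11 without June replicate 2, 437 without July replicate 1, 53 without July replicate 2 and 62 without July replicate 3. Without July replicate 1 the balance turned, with 160 genes higher and 277 lower. With June replicates 1 and 2 averaged 9 genes were called, and with only the arrays of these dates 3, of which 1 was higher and 2 lower. It was 210 without the 2 arrays that stood apart, 210 with the random slide block, 66 with the replicate block and 371 with the exchanged labels. June and July shared only the slide of the replicates numbered 3, with 1 array each, so a sign shared by all 116 called genes, which were chosen on the same arrays, is no separate test, and limma with slide as a fixed block called 0 genes.

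Between July and September no readable transcript passed. PtGA3PDH, named for the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase, did not pass over all genes (adjusted p = 0.0924) and was called lower when adjusted over the list alone. Its probe was well above background on no September array, so no size is given for the difference. Of the contigs, Ppnisotig12725_Q84TD6 rose by 4.09 ± 0.75 (adjusted p = 0.0436) and T-isotig16365_B9RT28 rose at least 17.2-fold from below background on all 3 July arrays (adjusted p = 0.0433). The log2 change of T-isotig16365_B9RT28 was 5.78 in the main fit and 3.1 with normexp and quantile normalization. C-isotig13633_BT111846 fell by 4.72 (adjusted p = 0.0436) and C-isotig06392_XP_002269039 by 3.18 (adjusted p = 0.0186). The last lost its call in 4 of 22 alternatives, while C-isotig13633_BT111846 did in 13 of 22, Ppnisotig12725_Q84TD6 in 15 of 22 and T-isotig16365_B9RT28 in 13 of 21, all 3 of them under the random slide block (adjusted p = 0.0575, 0.0863 and 0.0547) and the replicate block (0.0663, 0.0675 and 0.0615).

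A total of 43 genes were called, 9 higher and 34 lower in September, against 2513 at an unadjusted p below 0.05. The count was 507 without July replicate 1, 14 without July replicate 2, 16 without July replicate 3, and 1, 7 and 10 without September replicates 1, 2 and 3. The balance also turned, with 367 genes higher and 140 lower without July replicate 1, and 3 and 0 with only the arrays of these dates. With the labels of June replicate 3 and July replicate 3 exchanged limma called 0 genes, with 1703 at an unadjusted p below 0.05, and the named contigs had adjusted p from 0.145 to 0.389. The changes kept their sign, at 4.09 for Ppnisotig12725_Q84TD6 and 4.13 for T-isotig16365_B9RT28. C-isotig13633_BT111846 was at -3.96 and C-isotig06392_XP_002269039 at -2.39. The count was 65 without the 2 arrays that stood apart and 23 with the random slide block. July and September shared 2 slides, and across all genes the changes on them correlated at 0.026 (Spearman 0.029), although all 43 called genes, which were chosen on the same arrays, had the same sign on both. With slide as a fixed block 12 genes were called.

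September was compared with March as the last and the first date. Alpha-tubulin was higher in September, by 1.12 ± 0.34 on the log2 scale (SE; adjusted p = 0.0427), a call lost in 9 of 21 alternatives, among them median scaling (1.00, adjusted p = 0.0665) and each March array left out (adjusted p = 0.0544, 0.102 and 0.13). Ppterpp2c fell by 1.29 (adjusted p = 0.00949) and PsGapC1 by 1.17 (adjusted p = 0.0395), calls lost in 1 and 8 of 21. Over these alternatives the changes ranged from -1.5 to -0.85 for Ppterpp2c and from -1.46 to -0.78 for PsGapC1. No phytochrome, cryptochrome, actin or translation name passed. The contigs C-isotig06399_B9R8V6 and T-isotig14821_CBI40790, well above background on no March array, were at 2.65 ± 0.84 and 2.83 ± 0.68 in September (SD, n = 3), a rise of at least 1492-fold and at least 1694-fold. C-isotig10058_B9R992 fell by 6.39 on the log2 scale as fitted (adjusted p = 0.00667), with 1 September array above background, and C-isotig05898_D5ABC6 fell at least 77-fold (adjusted p = 0.0478). The latter varied widely in September (-3.63 ± 4.57), with a fitted change of -6.61 ± 2.06 (SE) that ranged from -8.31 to -4.02 over 20 alternatives. It lost its call in 11 of these, while the other 3 contigs lost theirs in none.

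In this contrast 2588 genes were called, 1601 higher and 987 lower in September, and a further probe had the same sign in 2452 of 2472. The balance of directions depended on the scaling: dividing by the array median gave 1406 higher and 1493 lower, and moved the median of all genes from -0.015 to -0.134. A total of 5412 genes had an unadjusted p below 0.05. The count was 1613 without March replicate 2, 1590 without September replicate 2 and 1347 without September replicate 3, and 3900 without April replicate 2 and July replicate 2. March and September arrays shared no slide, so slide and date cannot be told apart.

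Many of the genes called in April were also called in September. Both contrasts called 1236 genes as higher and 677 as lower, against 151.7 and 90.1 for independent lists of the same sizes, and the log2 changes correlated at 0.80 across genes, with a covariance of 1.23. As the contrasts share the March arrays, 20 simulations with no change were run, and these gave a correlation of 0.50, a covariance of 0.23 and 0 shared genes on average. With March divided so that 1 array served one contrast and the other two served the other, in all 6 ways, the correlation was 0.61 to 0.65 and the covariance 1.07 to 1.12. Limma then called 366 to 623 genes in both with one sign, against 44.1 to 61.2 for independent lists. Of the readable transcripts, Ppterpp2c and alpha-tubulin were called in both.

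**Figure D3:**
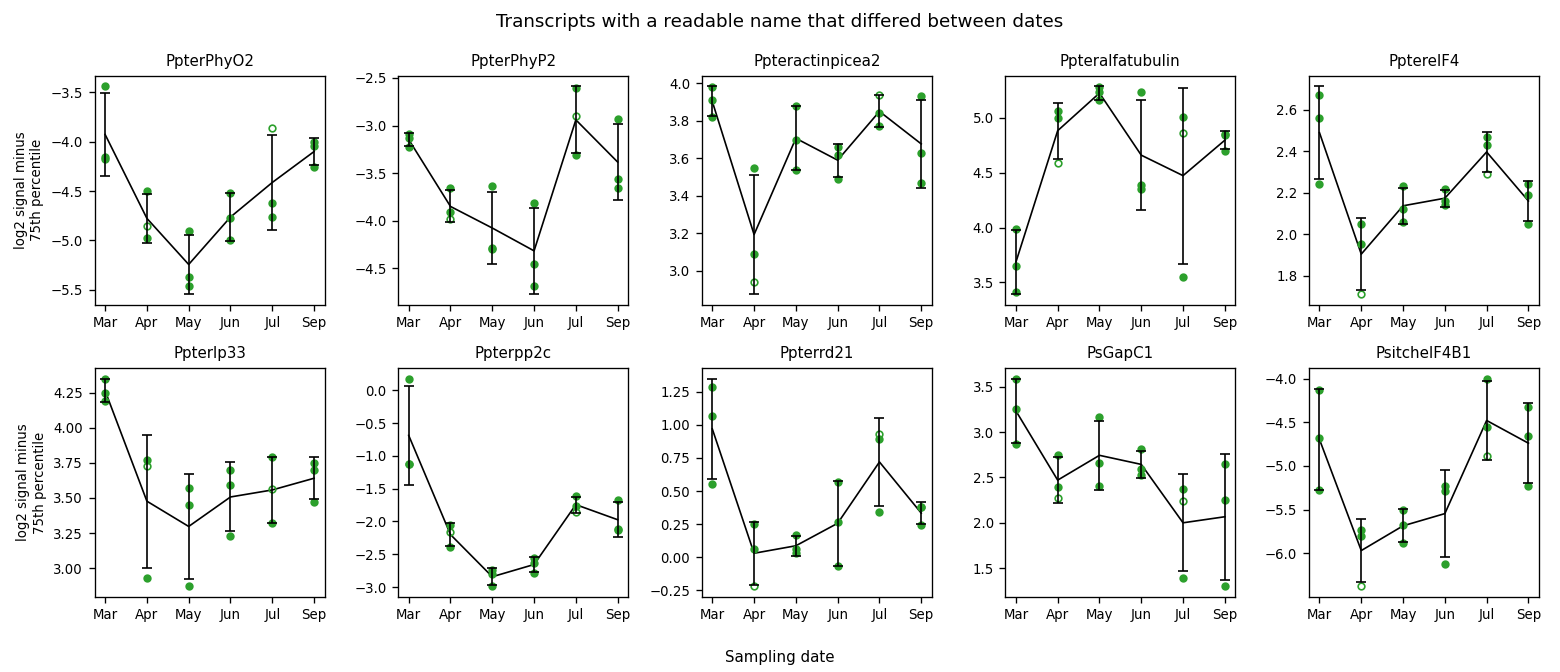
Levels of the 10 readable transcripts called in at least 1 contrast, as log2 signal minus the 75th percentile of the array against sampling date. Points are arrays (open for April replicate 2 and July replicate 2), and lines and bars are date means ± SD of 3 arrays; alpha-tubulin goes from 3.68 in March to 4.88 in April, and Ppterpp2c from -0.69 to -2.20.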

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

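The fits without the arrays that stood apart, those with June replicates 1 and 2 averaged, the division of the March arrays and the exchange of the labels of June replicate 3 and July replicate 3 were chosen after seeing the data. The groups by readable name were formed once the names were seen but before any value was compared between dates, and all other alternatives were chosen before the data were examined. The shift of the fixed gene lists was not run, as no list matched a gene, and the layout did not allow a fixed slide block for May minus April or September minus March. The self-test's recovery and the probes near background limit what was called. The cause of the changes below was not tested, except that the fits on fewer arrays had fewer samples.

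April minus March, the F test and September minus March stayed within 1.5 times of 3603, 3826 and 2588 under every scaling, filter, probe rule and variance model, under the random slide block and with June replicates 1 and 2 averaged. With slide as a fixed block June minus May called 0 genes, July minus June 0 and September minus July 12. The F test of that fit called 1704, but it covered only these contrasts and April minus March. As it left out differences of March and April from later dates, it cannot be set against 3826. With slide as a random block July minus June called 210 and September minus July 23. June minus May, with 1 gene, went to 0 with normexp, the strict filter, the deposited value table and June replicates 1 and 2 averaged, and to 2 with the mean of a gene's probes. With only the dates compared, the counts in date order were 1820, 7, 47, 3 and 3.

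Without the 2 arrays that stood apart, May minus April called 3, June minus May 5, July minus June 210, September minus July 65 and September minus March 3900. Without all 4 the F test called 6184, May minus April 6, June minus May 1911, July minus June 576 and September minus March 4810, and 2154 genes were highest in March in place of 1386; July then had 1 array, assumed to vary like the rest. With June replicates 1 and 2 averaged July minus June called 9 and September minus July 10, and with the 2 arrays left out as well May minus April called 2, June minus May 0, July minus June 25 and September minus July 25.

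Leaving out 1 array at a time gave 2119 to 4534 genes for the F test, 2304 to 2805 for April minus March, 0 to 1 for May minus April, 0 to 124 for June minus May, 9 to 437 for July minus June, 1 to 507 for September minus July and 1347 to 2100 for September minus March. It gave 617 to 1481 genes highest in March, and medians of 0.09 to 0.76 for the phytochromes and 0.40 to 0.89 for the cryptochromes in July minus June and -0.59 to -0.19 for SPI in May minus April.

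The camera calls were lost with an estimated correlation at the same medians (0.32, 0.65 and -0.46). In July minus June the phytochrome and cryptochrome calls were also lost with normexp (0.43 and 0.70), quantile normalization (0.47 and 0.66), no filter (0.32 and 0.65), the strict filter (0.26 and 0.65), the mean of probes (0.41 and 0.67), the deposited table (0.42 and 0.70), eBayes with trend (0.32 and 0.65), the random slide block (0.30 and 0.63) and the 2 arrays left out (0.09 and 0.40, or 0.24 and 0.49 with June averaged), and that of the cryptochromes with median scaling (0.72). Without 4 arrays camera's direction was down for both (medians 0.12 and -0.16). The SPI call was lost with the strict filter (-0.40) and with 2 or 4 arrays left out (-0.29, also with June averaged), as well as without April replicate 2, April replicate 3 or May replicate 2. Of 680 values for 32 named changes, 480 stayed on their side of the threshold, 195 lost the call, 5 gained one and 0 changed sign.

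With the replicate number as a replicate block, July minus June called 66 genes and June minus May 2, and the other counts stayed within 1.5 times. Whether the numbers pair the arrays was not settled. Deviations from the date means had a median correlation of -0.01 in pairs with the same number and 0.002 in other pairs. Of 45 pairs with the same number, 8 correlated above 0.1 (range -0.34 to 0.84). Among 18 arrays, 9 correlated best with an array of their own number, and no chance level was computed for this.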

Other observations

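The tests of a failed hybridisation, of a label exchanged with another date, of exchanged June and July labels, of the date each array lay nearest to, of a common slide effect and of shared positions were chosen only after the result was seen, while those on pairs of probes and on other splits of the arrays were chosen before.

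Several readable transcripts had date means that lay close together. The date means of Ptactin2 spanned 0.08 on the log2 scale, those of Pt40SS27 0.25, those of PpterUbiquitin 0.26 and those of Ppteractinpicea 0.27, and none of these passed the F test (adjusted p = 0.988, 0.869, 0.69 and 0.72). In contrast, the date means of PsGA3PDH and PthGA3PDH each spanned over 3 log2 units, lowest in March and highest in June, without passing (adjusted p = 0.196 and 0.233). The share of genes passing the F test was 19.4% for names beginning with C-isotig, 19.5% for T-isotig and 21.3% for both Ppisotig and Ppnisotig names. It was 12% for the SPI names (6 of 50) and 30.5% for the 59 names outside the prefix classes (18 genes), and these differences in share were not tested.

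April replicate 2 and July replicate 2 lay apart from the other 16 arrays, with 552 genes over 4 log2 units below and 79 above their mean on both, and the 79 argue against a weak or failed hybridisation. The highest correlation with an array of another date outside the pair was 0.785, below the lowest between replicates of the other arrays, 0.847. With their own dates these 2 arrays also lay below that, at most at 0.787 for April replicate 2 and 0.760 for July replicate 2. This test therefore cannot tell whether a label was exchanged with another date. The difference between the 2 probes of a gene can reflect how well the RNA matches each probe, though other sources of it were not tested. This difference correlated at 0.918 across genes between these arrays and at no more than 0.295 in other pairs, apart from June replicates 1 and 2. RNA of another sequence, such as another genotype or species, may therefore be a candidate explanation, as a hypothesis found on the same data. No biological explanation from the design was tested, as the arrays belong to different dates, and genes that truly differed in these samples remain possible.

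With July replicate 2 left aside, June replicate 3 lay nearer to July replicate 1, and July replicate 3 to June replicates 1 and 2, than to their own date, with a gain in correlation of at least 0.021. Exchanged labels may account for this, though June replicate 3 lay nearest to May (0.932), and July replicate 1 and September replicates 2 and 3 also lay nearer to another date. The split that exchanges them called 371 genes against 116 for the labels as given, so that count does not favour the labels as given. A common effect of their shared slide was checked in May and September. There replicate 3 differed in correlation from the other pair of its date by 0.01 and -0.019. The September value is close in size to the gain of 0.021, so this check cannot decide on a slide effect. Exchanged labels, a slide effect and a sample at another stage of growth than its date all remain open, the last untested.

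June replicates 1 and 2 were nearly identical, with an SD of differences of 0.314 against at least 0.89 for the pairs of replicates 1 and 2 on 1 slide in March, May and September, which argues against the shared slide as the whole cause. Their probe differences correlated at 0.6, against no more than 0.295 in other pairs outside April replicate 2 and July replicate 2. By Spearman correlation the gap was narrow, at 0.309 against 0.266 for April replicates 1 and 3. An explanation by 1 RNA or 1 tree on both arrays may be a candidate, though a weak one by Spearman correlation. Which of these holds was not tested, and if it does the dates hold fewer independent samples than arrays.

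Among 100 splits of the 18 arrays into 6 groups of 3, 1 split, the real one, gave as many genes in the F test as the 3826 found, and the highest of the others gave 1381. This argues against chance for that count only as far as the arrays can be exchanged. April replicate 2 and July replicate 2, alike across dates, and the nearly identical June replicates 1 and 2 may not meet that condition. For each contrast the 10 splits of its 6 arrays are too few for a share under 0.05. For April minus March 1 of the 10 splits gave as many genes as the real one (3603, highest other 1), for September minus March 1 (2588, highest other 1), for September minus July 1 (43, highest other 2), for June minus May 1 (1, highest other 0), for July minus June 2 (116, highest other 371) and for May minus April 10 (0, highest other 1).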
